A study of Homo sapiens with 3 samples.

How the data were processed

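Sequencing reads of 3 RIP-seq libraries of HHL5 cells were handled by the authors with CASAVA 1.4 and the human build hg38, both per the submitters' processing notes, and the aligner, the counting tool and its treatment of strand and of reads shared between genes are not given in the sources used here. The deposited table holds raw counts per gene, per the file headers, with Ensembl identifiers and names, and lists 13247 genes, all protein-coding. Its header describes 6 count columns, while 3 were in the table analysed here, 1 for each replicate. A further 3 per-sample columns, which the header calls normalised by edgeR, repeat the names of the count columns and were not used.

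Replicates were taken from the sample labels, and all 3 libraries belong to 1 group. Whether they came from separate cultures is not stated, so the spread between them may be technical. Counts were divided by each library's total and scaled to sum to 1000000 (CPM), and log2 values used a pseudocount of 1 CPM. A level per transcript length could not be formed from this table, so CPM took the place of the length-normalised values that had been planned where available. Current symbols and positions came from the NCBI RefSeq table of GRCh38, the same assembly as hg38, in which 12819 genes (96.8%) were found through their gene identifiers, and 734 symbols were updated. The span of a gene runs from its first to its last annotated base, introns included.

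Before the data were examined, 29 gene lists, the tests and the named genes were fixed. The named genes were DDX49, the 20 protein-coding genes of highest mean level outside the mitochondrially encoded, ribosomal protein and replication-dependent histone lists, the 10 highest genes of other biotypes (the table has none), the 3 highest members of each list with the number below 1 CPM, and the 5 genes with the largest SD of log2 level among those of at least 10 CPM. Where the text names further genes, such as list members near 0 counts, these were chosen after their values were seen. Some genes that the rule takes are not reported here. For each list of at least 5 members, the median log2 level in each library was compared with the median of all genes with a mean of at least 1 CPM. Its percentile was found among 10000 random lists of the same size drawn from these genes and the list's own members. The list kept its members below 1 CPM. A list was called above or below when it lay in the highest or the lowest 2.5% of these in each of the 3 libraries. No p-value was given for it, since a sign-flip test of 3 libraries cannot go below 0.25.

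Differences between libraries were tested per gene with a chi-square test of the 3 counts against the library totals, over genes with a summed count of at least 30, with Benjamini-Hochberg adjustment at 0.05. The coefficient of variation came from an intercept-only edgeR model with TMM factors of 1.026, 0.996 and 0.979. Shares of single libraries carry 95% Wilson intervals. Reads carried no molecular identifiers in the sources used here, so intervals and limits for 0 counts cover counting error only. The deepest library, replicate 1, has the smallest such error, with a median of 35 counts per gene against 24 and 18.

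The procedures were tested on simulated counts. Of 8636 genes drawn with no change, 0 were called, and with 200 genes changed in replicate 3, 75% of those changed 2-fold and 99% of those changed 4-fold were called, along with 10 unchanged genes. Of 200 random lists of 20 genes of at least 1 CPM, 7 were called above or below. That share does not cover lists with members below 1 CPM. Of the lists drawn from the genes of highest level 200 of 200 were called above, as their choice by level made near certain. A simulated coefficient of variation of 0.2 was recovered as 0.199. Alternatives were other pseudocounts, backgrounds, size factors and count minimums, random lists matched on span, and leaving out each replicate in turn. Leaving DDX49 out of the totals, and TMM scaling of levels, were added after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.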

Results

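RNA recovered with Flag-tagged DDX49, a DEAD-box RNA helicase with known roles in ribosomal RNA processing and mRNA export, was sequenced from cells that the labels give as HHL5, an immortalised human hepatocyte line. The identity of the line cannot be checked from these counts. The cells carried the Flag-DDX49 construct and had been kept for 24 h in 1.5 mM OA/PA at a ratio of 2 to 1, a mixture usually made of oleic and palmitic acid to load liver cells with fat. In RNA immunoprecipitation sequencing (RIP-seq) the protein is captured with an antibody, here against the Flag tag after ultraviolet cross-linking, and the RNA that comes with it is counted. The series held 1 group of 3 replicate libraries. Neither an input, a mock pull-down nor an untreated sample was among the libraries analysed here, so a transcript's level joins its abundance in the cell and its recovery with DDX49, and no comparison between conditions was made. The libraries held 2023133, 1461858 and 1096586 counts over 13247 protein-coding genes, and 11601, 11519 and 11237 genes had at least 1 count. A single count equalled 0.494, 0.684 and 0.912 CPM, the scale on which each library sums to 1000000, in replicates 1, 2 and 3.

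DDX49 itself was the most abundant transcript in the pull-down and the gene furthest above all others. It took 4.26% ± 0.787 of all counts (SD, n = 3), or 42565 ± 7866 CPM, which was 6.28 ± 1.17 times the level of the next gene. The gene (ENSG00000105671) lies on chromosome 19 at 18919715 to 18928630 (hg38), and its span overlapped 0 other protein-coding genes of the reference. Its 71443, 60602 and 55846 counts gave shares of 3.53% (95% Wilson interval 3.51 to 3.56), 4.15% (4.11 to 4.18) and 5.09% (5.05 to 5.13), so the replicates differed by more than counting error. The highest of the 30 other DEAD-box helicases of the fixed list found in the table, DDX3X, had 536 ± 50.9 CPM, and the median over these 30 genes was 70.8 CPM. That list leaves out EIF4A1 and EIF4A2, which were placed among the translation factors. DDX49 exceeded the highest other listed helicase by 79.6 ± 13.5-fold, with 64.1-fold as the lowest of the 3 libraries. The counts do not separate the cells' own DDX49 mRNA from RNA of the transfected construct.

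Below DDX49, the next 19 transcripts outside the mitochondrial, ribosomal protein and histone lists had means of 2810 to 6696 CPM. The iron storage subunit FTH1 (6696 ± 116 CPM, n = 3 here and below), the keratin KRT8 (6409 ± 619.5), the elongation factor EEF2 (6118 ± 449.8), the actin ACTB (5938 ± 135) and the keratin KRT7 (5813 ± 143) led the list. The actin ACTG1 (4597 ± 19.6), the myosin heavy chain MYH9 (4456 ± 55.95) and the cross-linking proteins FLNA (4395 ± 246) and PLEC (2810 ± 132) were further cytoskeletal genes. Among chaperones, CALR of the endoplasmic reticulum had 5353 ± 653 CPM, HSP90AB1 5131 ± 269 and HSP90AA1 3614 ± 25.9. The glycolytic enzymes GAPDH (4075 ± 99.4), ENO1 (3779 ± 158) and PKM (3238 ± 99.1) were followed by the secreted chaperone CLU (2833 ± 334). At the cell surface, the growth factor receptor EGFR had 3525 ± 201 CPM, the amino acid transporter subunit SLC7A5 2814 ± 299 and the placental alkaline phosphatase ALPP 3669 ± 75.3. Between replicates, 13 of these 20 genes, DDX49 included, differed by more than counting error, and the other 7 (FTH1, ACTB, ACTG1, MYH9, GAPDH, ALPP and HSP90AA1) did not pass that test. How reads shared by close paralogs, as in the actin, HSP90 and alkaline phosphatase families, or by pseudogenes were counted is not given in the sources used here, so the split within such families is uncertain.

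**Figure D1:**
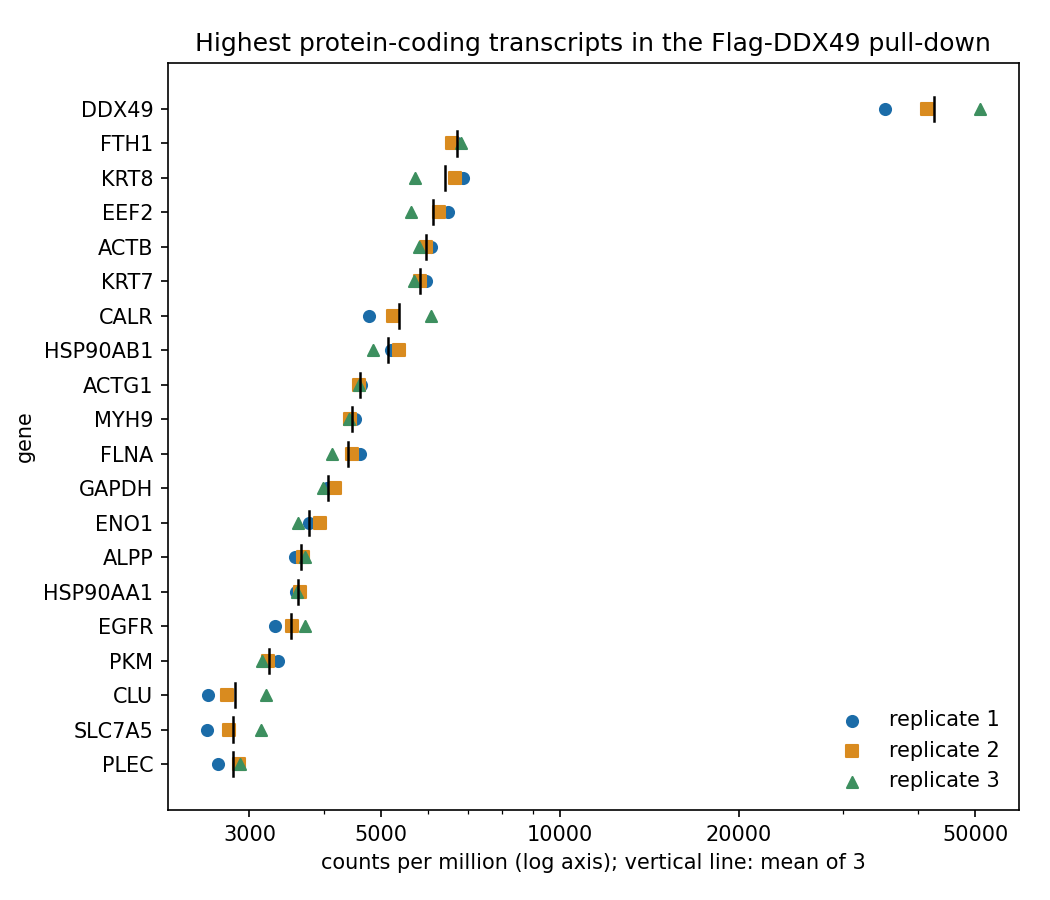
Level of the 20 most abundant protein-coding transcripts outside the mitochondrial, ribosomal protein and histone lists, in CPM on a log axis. Points are the 3 replicates and the vertical lines their means, with DDX49 at 42565 and the next gene, FTH1, at 6696.

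Transcripts of the translation machinery and of DEAD-box helicases lay above the background. The median ribosomal protein transcript lay 4.05 ± 0.18 log2 units above the median of the 10815 background genes (mean of at least 1 CPM), led by RPL19 (2734 ± 165 CPM), RPL23A (2087 ± 263) and RPL8 (2075 ± 111), and the 77 genes together took 4.92% ± 0.254 of the counts. Translation factors lay 3.16 ± 0.08 above, with EEF2, EEF1A1 (1580 ± 87.2) and EIF4B (1338 ± 153) highest. Ribosome biogenesis factors lay 1.50 ± 0.17 above, with the nucleolar proteins NCL (1618 ± 105), NPM1 (1538 ± 94.7) and NOLC1 (624 ± 65.2) highest. DEAD-box helicases lay 1.58 ± 0.13 above, with DDX3X and the splicing helicase DDX23 (412 ± 43.6) next after DDX49. That list holds DDX49 itself, and with DDX49 left out of counts and totals it lay 1.41 ± 0.10 above, at percentiles 99.6 to 99.87. Each of these lists passed the preset limit, a median in the highest 2.5% of 10000 random lists of the same size in all 3 libraries; the lower limit was set alike. The lists kept members below 1 CPM, while the random lists could draw such genes only from the list's own members. The lower limit is therefore easier to pass than with no filter on the background. With the background restricted to genes of at least 10 CPM, ribosome biogenesis factors (0.71 ± 0.16) and DEAD-box helicases (0.79 ± 0.14) no longer passed. Of the 77 ribosomal protein genes 4 had a mean below 1 CPM, among them RPL5, RPL36A and RPS9, as did the translation factor EEF1G, which had 0 counts in each library. A count of 0 allows up to 1.48, 2.05 and 2.74 CPM in replicates 1, 2 and 3 (3 counts of the total).

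Transcripts of proliferation and respiration also passed the upper limit. Proliferation genes lay 2.59 ± 0.12 above the background, with the cycling marker MKI67 (1446 ± 50.8 CPM), the mitotic transcription factor FOXM1 (903 ± 62.1) and the replication helicase subunit MCM3 (699 ± 27.9) highest, and 0 of the 23 members had a mean below 1 CPM. Nuclear genes of oxidative phosphorylation lay 1.82 ± 0.06 above, led by SDHA (827 ± 113), ATP5F1B (636 ± 32.6) and COX4I1 (582 ± 54.99), and 1.04 ± 0.07 above a background of at least 10 CPM. The 6 mitochondrially encoded genes in the table lay 4.01 ± 0.35 above, with MT-CO3 (3679 ± 614), MT-ND2 (3134 ± 645) and MT-ND5 (2056 ± 433) highest, while MT-CO1 had 0.633 ± 0.550 CPM. Their share of the counts was 0.905% ± 0.172, with 0.742%, 0.887% and 1.09% in replicates 1, 2 and 3. Replication-dependent histones took 0.813% ± 0.032 of the counts and did not pass the limit (0.88 ± 0.36), with the linker histones H1-4 (1526 ± 122) and H1-2 (1459 ± 126) and the core histone H2BC12 (533 ± 33.9) highest. The histone list fell short in replicate 1 alone, so it had to pass without it (1.07 ± 0.21), since each library is ranked on its own. It passed with no filter on the background (1.52 ± 0.37), and lay at 0.10 ± 0.36 against a background of at least 10 CPM.

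Markers of mature hepatocytes were near 0 in the pull-down, with the exception of CPS1. Of the 22 hepatocyte markers 8 were in the table, 6 of these had a mean below 1 CPM, and their median passed the lower limit, at -4.66 ± 0.22 log2 units from the background median. That distance is set by the pseudocount, since the list median was below 1 count in each library, and it was -7.57 ± 0.86 with a pseudocount of 0.1 CPM. With no filter on the background the list still passed (-4.02 ± 0.24). CPS1, the first enzyme of the urea cycle, had 1726 ± 45.9 CPM, against 1.72 ± 0.317 for the transcription factor CEBPA and 0.912 ± 1.58 for the apolipoprotein APOA2. Of the 9 biliary and progenitor markers in the table KRT8, KRT7 and KRT18 (2608 ± 127) were highest and KRT19 had 0 counts, the median member had 10.9 CPM, and the list did not pass either limit (-0.94 ± 0.35). Stellate cell and fibroblast markers did not pass either (-1.55 ± 0.64), with the intermediate filament VIM at 1104 ± 52.5 CPM, COL3A1 at 42.5 ± 9.59 and PDGFRB at 31.1 ± 8.90. Of 11 endothelial markers 2 were in the table, ENG (154 ± 7.58) and CDH5 (3.07 ± 3.34), and of 14 immune cell markers 1, CD14, with 0 counts. The endothelial and immune lists were too short to be ranked. Against a background of at least 10 CPM, the biliary (-1.72 ± 0.34) and stellate cell (-2.33 ± 0.66) lists passed the lower limit. That background lacks genes below 10 CPM while the lists keep theirs, which makes the lower limit easy to pass. With no filter on the background neither list passed (-0.29 ± 0.32 and -0.91 ± 0.67).

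No list of lipid handling passed a limit with each of the 3 backgrounds tried. Fatty acid and triglyceride synthesis was led by the desaturase SCD (1929 ± 117 CPM), the fatty acid synthase FASN (1396 ± 102) and the citrate lyase ACLY (611 ± 51.8), and its median lay 0.87 ± 0.09 from the background median, at percentiles 90.59 to 93.62. Cholesterol synthesis and uptake lay 1.33 ± 0.22 above at percentiles 96.97 to 99.47, just short of the limit in replicate 1 alone. Leaving that replicate out (1.46 ± 0.05) had to give a pass, since each library is ranked on its own. Lipid droplet and lipolysis genes passed the lower limit in the main comparison (-2.18 ± 0.32), whose background holds no genes below 1 CPM. In that list 6 of 14 members were below 1 CPM, among them PLIN1, PLIN5 and CIDEC, and PLIN3 (360.2 ± 30.4), the lipase MGLL (186 ± 23.8) and PNPLA2 (74.8 ± 16.1) were highest. Fatty acid uptake and binding (-0.71 ± 0.33) passed neither limit, with SLC27A4 at 93.8 ± 17.3, ACSL3 at 86.9 ± 20.5 and SLC27A2 at 66.7 ± 5.11. Fatty acid oxidation (0.03 ± 0.14) lay at the background median, with ACADVL (365 ± 10.01), HADHA (271 ± 16.1) and the carnitine transferase CPT1A (247 ± 34.8) highest. With no filter on the background, and so with such genes on both sides, the lipid droplet list did not pass (-1.53 ± 0.33, percentiles 4.78 to 13.5), while the synthesis (1.51 ± 0.06) and cholesterol (1.98 ± 0.21) lists passed the upper limit. Against a background of at least 10 CPM, synthesis (0.08 ± 0.07), cholesterol (0.55 ± 0.21) and oxidation (-0.75 ± 0.15) passed neither limit, and fatty acid uptake and binding passed the lower one (-1.50 ± 0.32). That background lacks genes below 10 CPM while the uptake list keeps its own, and with no filter the list passed neither limit (-0.07 ± 0.30).

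Among stress and signalling genes, chaperones of the endoplasmic reticulum were the most abundant. The unfolded protein and integrated stress response list lay 1.24 ± 0.15 above the background at percentiles 96.54 to 99.01. It fell short in replicate 1 alone, so it had to pass with that replicate left out (1.33 ± 0.01). With no filter on the background it passed as well (1.89 ± 0.15). Against a background of at least 10 CPM it lay at 0.46 ± 0.14 and did not pass. The chaperones HSP90B1 (1713 ± 342 CPM) and HSPA5 (1096 ± 129) and the disulfide isomerase PDIA4 (691 ± 42.5) were its highest members. Immediate early genes (0.24 ± 0.16, or -0.55 ± 0.14 against at least 10 CPM) did not pass, with MYC at 864 ± 30.4, IER3 at 757 ± 22.3 and the phosphatase DUSP1 at 288 ± 5.33. Inflammatory mediators passed the lower limit in the main comparison (-2.20 ± 0.23), with 3 of 12 members below 1 CPM. The inhibitors NFKBIA (263 ± 9.59) and TNFAIP3 (45.4 ± 11.997) and the subunit NFKB2 (98.97 ± 11.9) were highest there, and IL1A, IL1B and IL6 were below 1 CPM. With no filter on the background, and so with such genes on both sides, the list did not pass (-1.55 ± 0.23, percentiles 7.01 to 12.4). Export factors of mRNA (0.67 ± 0.03, or -0.12 ± 0.05 against at least 10 CPM) passed neither limit, with NUP98 (380.1 ± 53.7), TPR (316 ± 14.2) and THOC5 (131 ± 10.3) highest. Of the snoRNA host genes 1 was in the table, SNHG32 (52.6 ± 3.47), and small nucleolar, small Cajal body, long noncoding, small structured and ribosomal RNAs were not analysed here.

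**Figure D2:**
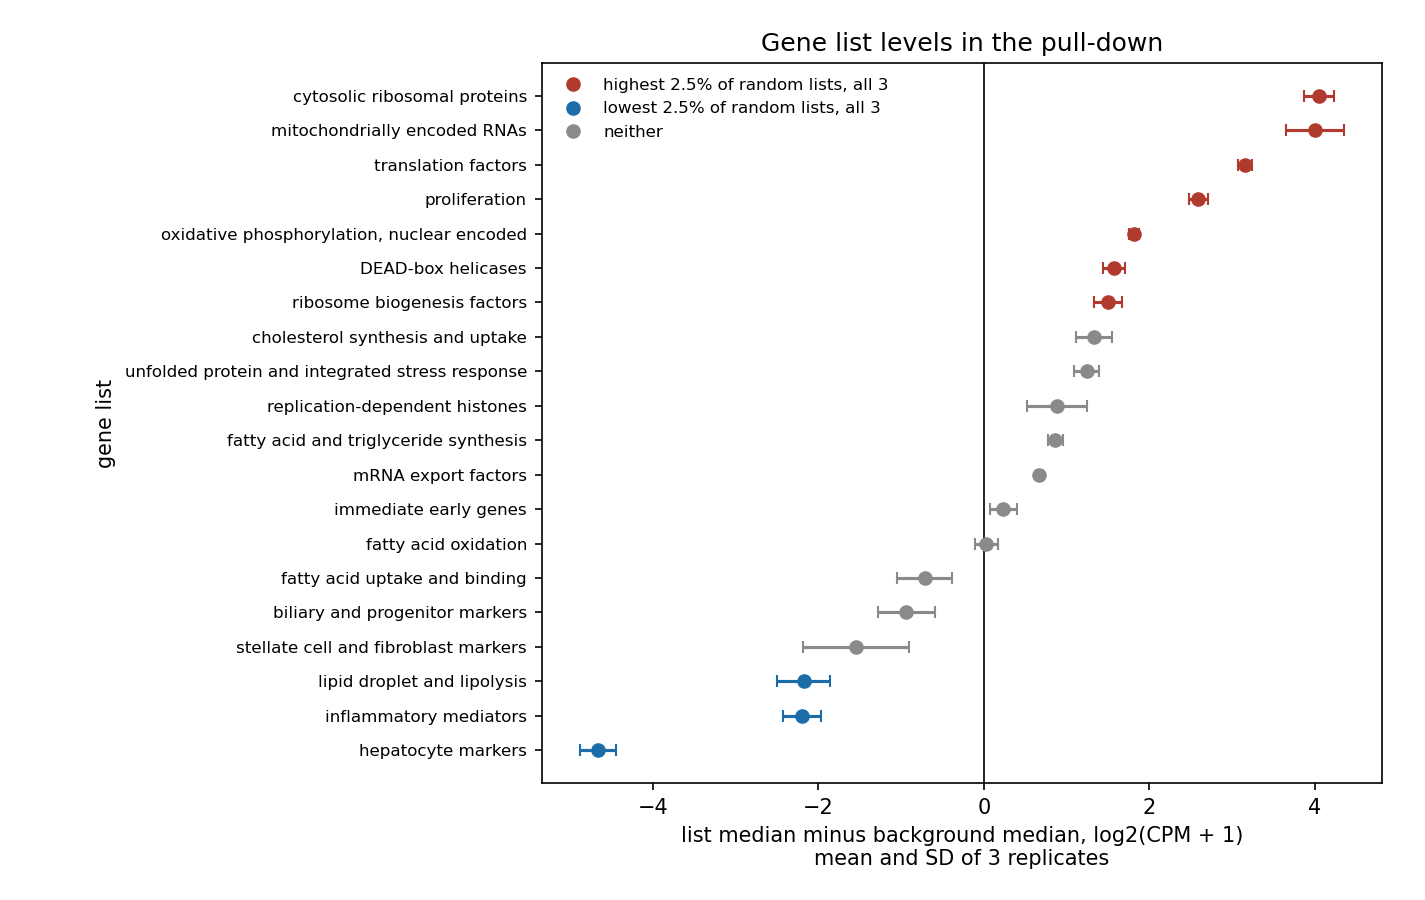
Median level of each gene list minus the median of the background genes on the log2(CPM + 1) scale. Points are means and bars SDs of the 3 replicates, coloured by whether the list passed the upper limit (7 lists), the lower limit (3) or neither (10). Genes below 1 CPM are in the lists and not in the background.

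The replicates ranked genes alike, and 4 of the 5 most variable genes encoded histones. Pearson correlations across the 10815 background genes were 0.963, 0.941 and 0.948 for the pairs 1 and 2, 1 and 3, and 2 and 3, with Spearman correlations of 0.970, 0.954 and 0.959. Genes are not independent replicates, so these describe the libraries only. The biological coefficient of variation was 14.6%. Of 8633 genes with a summed count of at least 30, 1691 (19.6%) differed between libraries by more than counting error at a Benjamini-Hochberg threshold of 0.05 in a chi-square test. With 2 libraries this number was 505 without replicate 1, 1322 without replicate 2 and 474 without replicate 3. That test compares libraries of 1 group, not conditions. Most variable among genes of at least 10 CPM were the core histones H4C14 (SD 2.99 log2 units, with 2, 99 and 81 counts), H2AC18 (2.52, with 22, 263 and 340), H4C11 (2.13, with 107, 3 and 24) and H3C14 (1.89, with 10, 93 and 54). The ion channel TMEM175 was the only one of the 5 outside the histones (1.60, with 31, 31 and 2 counts). H4C14, H2AC18 and H3C14 lie in 1 cluster on chromosome 1 (hg38), at 149832657 to 149833052, 149842218 to 149842750 and 149840687 to 149841208, and H4C11 lies on chromosome 6 at 27824092 to 27824480. These histone genes have near-identical copies that can share reads, so their single values are uncertain.

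Level showed almost no rank correlation with the length of the gene's locus. Spearman correlations between log2 level and genomic span, introns included, were 0.00318, -0.00304 and -0.0146 across 10555 genes in replicates 1, 2 and 3. In 5 groups of about equal size, with genes ordered by span, median levels lay between 27.1 and 27.7 CPM. Transcript lengths were not used here, so levels of genes with long and short transcripts are not on a common scale per molecule.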

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

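Leaving DDX49 out of the totals and TMM scaling of levels were tried after seeing the data; all other alternatives were planned. The 20 most abundant genes were the same under all 5 alternatives tried for them, and no called result reversed. In 182 comparisons of a main result with an alternative, it kept its call or, where it has none, moved by less than the bound set for it. It was weaker in 6, stronger in 10 and moved past its bound in 5. Many of the 182 could hardly come out otherwise, so their number does not measure robustness. Another pseudocount keeps the order of genes, and a list that passed in 3 libraries keeps its call when 1 is left out. Leaving DDX49 out of the totals raises every other gene of a library by 1 factor. With a background of at least 10 CPM, fatty acid uptake (-1.50), biliary (-1.72) and stellate cell markers (-2.33) passed the lower limit, and ribosome biogenesis (0.71) and DEAD-box helicases (0.79) lost the upper one, while fatty acid synthesis (0.08), cholesterol (0.55), the stress response (0.46), histones (0.10), fatty acid oxidation (-0.75), immediate early genes (-0.55) and mRNA export (-0.12) passed neither, the last 3 being positive in the main analysis. With no filter, fatty acid synthesis (1.51), cholesterol (1.98), the stress response (1.89) and histones (1.52) passed the upper limit, and lipid droplet (-1.53) and inflammatory genes (-1.55) lost the lower one, since the median of the background moves with its filter and only this setting has genes below 1 CPM on both sides. Fatty acid uptake, biliary and stellate cell markers passed no limit there. Their lower calls at 10 CPM set lists with members below 10 CPM against a background without such genes. Leaving out 1 replicate, cholesterol ranged from 1.25 to 1.46, the stress response from 1.199 to 1.33 and histones from 0.71 to 1.07, and all 3 passed the upper limit without replicate 1, the library in which they had fallen short. These passes were fixed in advance, since each library is ranked on its own. The lowest Pearson correlation was 0.961 with no filter and 0.8895 with a pseudocount of 0.1. Leaving out 1 replicate it ranged from 0.941 to 0.963, and the biological coefficient of variation from 11.5% to 18.4%. The number of genes past the chi-square threshold ranged from 474 without replicate 3 to 1322 without replicate 2, against 1691 in 3 libraries, so it depended on which library was left out. The correlation with span was -0.0328 among genes of at least 10 CPM. The cause was not tested for these. Length-normalised values were planned and not run, as the table gave none used here. No paired analysis was possible because there is 1 group. Depth limits genes below about 1 CPM, where replicate 3 gives about 1 count.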

Other observations

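The tests in this part of annotation terms, of differences of lists between replicates, of the DDX49 construct, of the histone copies gene by gene and of genes chosen by their values were chosen after the results were seen. Among 282 annotation terms with at least 30 members of at least 1 CPM, 140 lay in the highest 2.5% of random lists by level in all 3 libraries and 8 in the lowest 2.5%. Unlike the fixed lists, the terms left out their members below 1 CPM, so the levels of terms and lists are not comparable. Besides the ribosome, the high terms included the brush border (3.28 ± 0.07 log2 units above the background median, n = 3), the melanosome (3.21 ± 0.15), stress fibers (2.32 ± 0.06), the basement membrane (2.19 ± 0.09), focal adhesions (2.15 ± 0.02) and the proteasome complex (1.72 ± 0.07). The 8 low terms were receptors of neuroactive ligands (-1.76 ± 0.21), the ciliary tip (-1.18 ± 0.11), the axoneme (-1.03 ± 0.16), the cilium (-0.82 ± 0.05), the primary cilium (-0.76 ± 0.05), the proteinaceous extracellular matrix (-0.88 ± 0.10), the extracellular region (-0.44 ± 0.10) and the broad term intracellular (-0.47 ± 0.06), while the related terms extracellular matrix (0.89 ± 0.04) and extracellular space (0.49 ± 0.05) were among the high ones. As 140 of the 282 terms were high, that call says little about a single term, and no background of at least 10 CPM was tried for them. Without an input library these levels do not separate recovery with DDX49 from abundance. The phosphatases ALPP (3669 ± 75.3 CPM), ALPI (199 ± 17.2) and ALPG (28.9 ± 5.77) are close paralogs, and their reads are not separated with certainty. The cell cycle inhibitor CDKN2A had 284 ± 23.05 CPM and the kinase STK11 had 0 counts in each library. The 0 of STK11 may be a matter of counting, and only 8 of the 22 hepatocyte markers were in the table. No other profile of the line was compared with these values. How far the culture matches a hepatocyte line was therefore not tested here and cannot be settled from these counts.

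Replicates 1 and 3 were the pair of libraries with the most annotation terms apart. Relative to random lists matched on level, 26 terms were low in replicate 1 and high in replicate 3, and 11 were high in replicate 1 and low in replicate 3. Among the other pairs, 7 terms were low in replicate 2 and high in replicate 3, 2 were low in replicate 3 and high in replicate 2, 1 was low in replicate 2 and high in replicate 1, and 0 were low in replicate 1 and high in replicate 2. The lysosomal lumen stood at -0.11 and 0.14 log2 units from its own mean in replicates 1 and 3, the Golgi lumen at -0.12 and 0.14, and N-glycan biosynthesis at -0.12 and 0.12. The nuclear pore went the other way, at 0.10 and -0.14, as did ErbB signalling, at 0.13 and -0.13. A shift of 0 is not the baseline here, since the nucleus term, with 3543 members, itself stood at 0.057 and -0.045. The terms were therefore called by percentile and not by the size of the shift. Of the fixed lists, mitochondrially encoded genes stood at -0.29 and 0.30, immediate early genes at -0.16 and 0.14, the unfolded protein and integrated stress response at -0.09 and 0.12, and ribosomal proteins at -0.09 and 0.09. Among terms of mitochondrial proteins, oxidative phosphorylation passed both limits, at percentiles 2.10 and 99.5 in replicates 1 and 3. The fixed list of nuclear oxidative phosphorylation genes, at 23.6 and 95.2, passed neither. The mitochondrial inner membrane (14.7 and 91.6), the mitochondrion (99.5 and 7.50) and the mitochondrial matrix (95.1 and 0.5) leaned different ways without passing both limits. HSP90B1 had 1389, 1681 and 2070 CPM in replicates 1, 2 and 3, and CANX, another chaperone of the endoplasmic reticulum, had 2165, 2370 and 2696. With DDX49 left out of counts and totals, the mitochondrially encoded list stayed at percentiles 0 and 100 in replicates 1 and 3. An unequal DDX49 share moves all other genes of a library by 1 factor, so it could hardly change these percentiles. Since all 3 libraries received the same treatment, no biological explanation was tested.

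The spread of single genes beyond counting error has several candidate explanations: a larger DDX49 share in replicate 3 lowers every other gene's CPM there, yet with DDX49 left out of counts and totals 94.1% of the 1691 genes were still called, which argues against this as the whole cause. Duplicate reads inflate spread by about the same factor at every depth. The median index of dispersion in the highest of 5 groups of genes by count was 1.66 times that of the lowest group (bootstrap 95% interval 1.53 to 1.81). That ratio lay just above the preset bound of 1.5. Over the 5 groups in rising order, the median index was 2.33, 2.39, 2.64, 2.89 and 3.88 times the counting expectation. Summed counts were 30 to 68 in the lowest group and at least 546 in the highest. The rise argues against duplicates as the whole cause. It was small beside the rise in counts, so how much of the spread duplicates make up stays open. If reads were divided between the listed near-identical copies, the copies would lose what the gene gains between its lowest and its highest library, but they lost 0.0146 of the gain in CPM of H4C14, 0.0211 of that of H2AC18 and 0.0268 of that of H3C14 (upper 95% limits 0.0522, 0.0416 and 0.214), which argues against this as the whole cause for these, while the copy of H4C11 lost 2.02 times its gain (1.53 to 2.67), which leaves it open there. Totals of the histone families in replicates 1 and 3 were 448 and 415 CPM for H4 and 1333 and 1623 for H2A. For H3 they were 792 and 794 in replicates 1 and 2, between which H3C14 rose. Exchange with family members beyond the listed copies was thus not excluded for H4C14 and H3C14. The planned test of reads shared between near-identical copies, by the SD after summing them, was void because a steady copy lowers an SD on the log scale (2 of the 4 genes fell under the bound). Differences in how each library was pulled down and prepared stay open, as the labels give no batches.

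DDX49 exceeded every other listed DEAD-box helicase by at least 64.1-fold in each library. Reads from the transfected construct could give this, and so could recovery of the DDX49 mRNA by its own protein. These cannot be told apart, since every library here came from transfected and pulled-down cells. Counts split by coding sequence and untranslated regions would bear on it, as a construct often lacks the latter.

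Several members of abundant families were close to 0 counts. Of the 136 genes of the ribosomal protein, translation factor and nuclear oxidative phosphorylation lists, 11 had a mean below 10 CPM, among them EEF1G (0 counts), RPL5 (0.165 ± 0.285 CPM), RPS9 (0.393 ± 0.353), NDUFB8 (0.558 ± 0.506) and EIF4A1 (2.77 ± 2.34). If reads were dropped where another protein-coding gene overlaps, the low members would overlap more often. Of them 36.4% did (4 of 11) against 16% of the other 125, with a one-sided Fisher's exact p of 0.104. Of the low members RPL17, RPL36A and RPS10 each overlapped a protein-coding gene with a read-through name in the reference, as no other member of these lists did. Read-through genes that are not listed there as protein-coding were not looked at. That split was seen after the test, which pooled all overlaps. Over the whole table, 17.2% of the 3077 genes that overlap another lay below 1 CPM, against 17.8% of the others. The share below 1 CPM was thus no larger with overlap, though the median level was lower, at 15.2 against 18.2 CPM. The cut of 1 CPM differs from the 10 CPM used for the families, so whether overlap costs reads stays open. If reads were shared with pseudogenes, the low members would have more of them, and their median was 13 pseudogenes of their name against 8 (one-sided permutation p = 0.198). For the 11 genes as a set neither explanation can be excluded or singled out. Until the counting rule is known, a value near 0 in this table, such as that of STK11 or KRT19, may be a matter of counting.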
